A study of Mus musculus with 40 samples.

How the data were processed

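RNA from the left lungs of 40 mice was sequenced after ribosomal RNA depletion with a stranded kit, in 8 groups of 5 mice. Per the submitters' processing notes, reads were aligned with STAR 2.6.1d, handled with Picard and counted per gene with featureCounts of Subread 1.6.3, and edgeR was used for normalisation. The notes name the builds mm9 and GRCm38, and the identifiers of the tables were joined to GENCODE M21 on GRCm38. The strand setting of the counting step is not given in the sources used here, so reads over overlapping or antisense genes and over close paralogs are uncertain.

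The deposited tables hold values in the unit count, one whole-number count per gene and library, for 55536 genes in each model. The authors also gave a shorter table per model that is named as TMM normalized. Its values were compared with the count table, and 14832 of 14832 genes in the bleomycin model and 14856 of 14856 in the Ad-TGFβ1 model were identical to the counts. A fit with limma-trend on the authors' TMM values was planned and was not run, because the shorter tables hold raw counts.

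All computing was done in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were filtered with filterByExpr by group, libraries were scaled by TMM, and edgeR's quasi-likelihood test was run with 1 coefficient per group and no covariate. The 4 groups of a model were fitted together, and all 40 libraries for the comparisons between models. P-values were adjusted by Benjamini and Hochberg over all genes tested, and a gene was called at an adjusted p under 0.05. CPM uses the TMM-scaled totals, and log2 CPM has a prior count of 2. The 10 comparisons were bleomycin in vehicle lungs, Ad-TGFβ1 in vehicle lungs, saracatinib in each of 4 kinds of lung, the interaction in each model, and the differences between models in the injury and saracatinib effects.

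The comparisons, tests, gene panel, gene lists and other settings were fixed before the data were examined. The genes named are the panel of 14, the 8 called genes with the largest change on each side that had a mean of at least 1 CPM, a gene name and no overlap between groups, and up to 4 called members of each called list. For interactions and differences between models 5 on each side were named, with no rule on overlap, and genes of immunoglobulin and T cell receptor segments were not named. There were 49 gene lists, written from general knowledge, and a list needed 3 tested members. Lists were tested with camera at a preset correlation of 0.01, then with an estimated correlation, and with fry. Correlations of effects across genes were compared with 20 simulations of unchanged groups, in which each gene was drawn independently, and with 20 splits of the shared vehicle libraries.

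Other settings fixed in advance were DESeq2's size factors, no low-count filter, DESeq2, limma voom with quality weights, Xist as a covariate, only the compared groups, and leaving out each library in turn. Xist had at most 12 counts in any library, so as a covariate it could not adjust for sex. Added after the data were seen were fits without the 2 libraries of each model farthest from their group, with only the genes of the shorter table, and with the ciliated or the clock score as a covariate. For chance, 100 groupings of the libraries were run per comparison, the true one among them. Each comparison had its own fixed seed, counted up from a base of 1. A count within a ratio of 1.5 was taken as unchanged.

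Total counts ran from 8.81 to 17.3 M per library, and TMM factors from 0.949 to 1.04. Over 80 pairs of replicates, the chi-square per degree of freedom of genes with at least 20 counts ran from 4.29 to 52.7, where counting noise alone would give 1. The 10 most abundant genes took 5.62 to 9.86% of the counts of a library, and the top gene 1.52 to 3.94%. The tests were also tested on simulated data with 200 changed genes. edgeR recovered 51, 51, 53 and 55% of genes changed 1.5-fold and 70, 74, 78 and 70% of those changed 2-fold, in the bleomycin, saracatinib in bleomycin, Ad-TGFβ1 and saracatinib in Ad-TGFβ1 designs, with 6, 8, 4 and 6 false calls. DESeq2 recovered 62, 63, 58 and 61% at 1.5-fold with 28, 24, 21 and 22 false calls.

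All 40 libraries were kept, except in the fits described above that left libraries out. Animal numbers and sex were not used, and the raw reads were not analysed here. Results of 3 of the named genes are not reported here.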

Results

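The series measured RNA in the left lungs of 40 C57BL/6 mice from a pair of models of pulmonary fibrosis, with 8 groups of 5 mice. In the bleomycin model, mice received saline or 1.5 U/kg of bleomycin, a DNA-damaging drug, by the oropharyngeal route. In the Ad-TGFβ1 model, mice received an empty adenoviral vector or an adenovirus carrying mouse Tgfb1 by the nose. In each model, mice were then gavaged daily from day 10 to day 27 with vehicle or 20 mg/kg of saracatinib, an inhibitor of Src family kinases, and lungs were taken on day 28 after 18 days of treatment. The labels give the effects of saracatinib in pulmonary fibrosis as the question. Total counts per library, in megacounts (M), were 9.51 to 13.7 M in the saline vehicle group, 8.81 to 16.3 M with saline and saracatinib, 11.4 to 17.3 M with bleomycin and vehicle, and 12.7 to 13.9 M with bleomycin and saracatinib. In the other model they were 9.29 to 12.5 M with empty vector and vehicle, 9.86 to 16.0 M with empty vector and saracatinib, 10.3 to 17.3 M with Ad-TGFβ1 and vehicle, and 10.2 to 12.7 M with Ad-TGFβ1 and saracatinib. After the filter on low counts, 18846 genes were tested in the bleomycin model and 18834 in the Ad-TGFβ1 model. The first principal component held 48.4% of the variance in the bleomycin model and 28.9% in the Ad-TGFβ1 model. All changes are log2 fold changes, and all adjusted p-values of single genes come from edgeR's quasi-likelihood test. Standard errors of single genes come from that test too. It shares its estimate of spread over all libraries of a model, or all 40 between models. Standard errors of the score differences come from the 5 libraries of each group compared. The clock and ciliated scores, their tests and their use as covariates were chosen after the results were seen.

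A panel of 14 genes was named before the data were examined. On the mouse genome build GRCm38, in the GENCODE M21 annotation, Col1a1 (ENSMUSG00000001506), a chain of collagen I, lies on chromosome 11 from 94936224 to 94953042. Col3a1 (ENSMUSG00000026043), the chain of collagen III, lies on chromosome 1 from 45311538 to 45349706, and Fn1 (ENSMUSG00000026193), which encodes fibronectin, on chromosome 1 from 71585520 to 71653200. Cthrc1 (ENSMUSG00000054196), a secreted protein of activated fibroblasts, lies on chromosome 15 from 39076932 to 39087121. Timp1 (ENSMUSG00000001131), a metalloproteinase inhibitor, lies on chromosome X from 20870166 to 20874735, and Mmp12 (ENSMUSG00000049723), the macrophage elastase, on chromosome 9 from 7344381 to 7369499. Tgfb1 (ENSMUSG00000002603), the cytokine carried by the adenovirus, lies on chromosome 7 from 25687002 to 25705077, and Src (ENSMUSG00000027646), a kinase that saracatinib inhibits, on chromosome 2 from 157418444 to 157471862. Each of the 14 is annotated as a protein-coding gene, and the counts are sums over a gene, so no value belongs to a single exon or untranslated region.

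**Figure D1:**
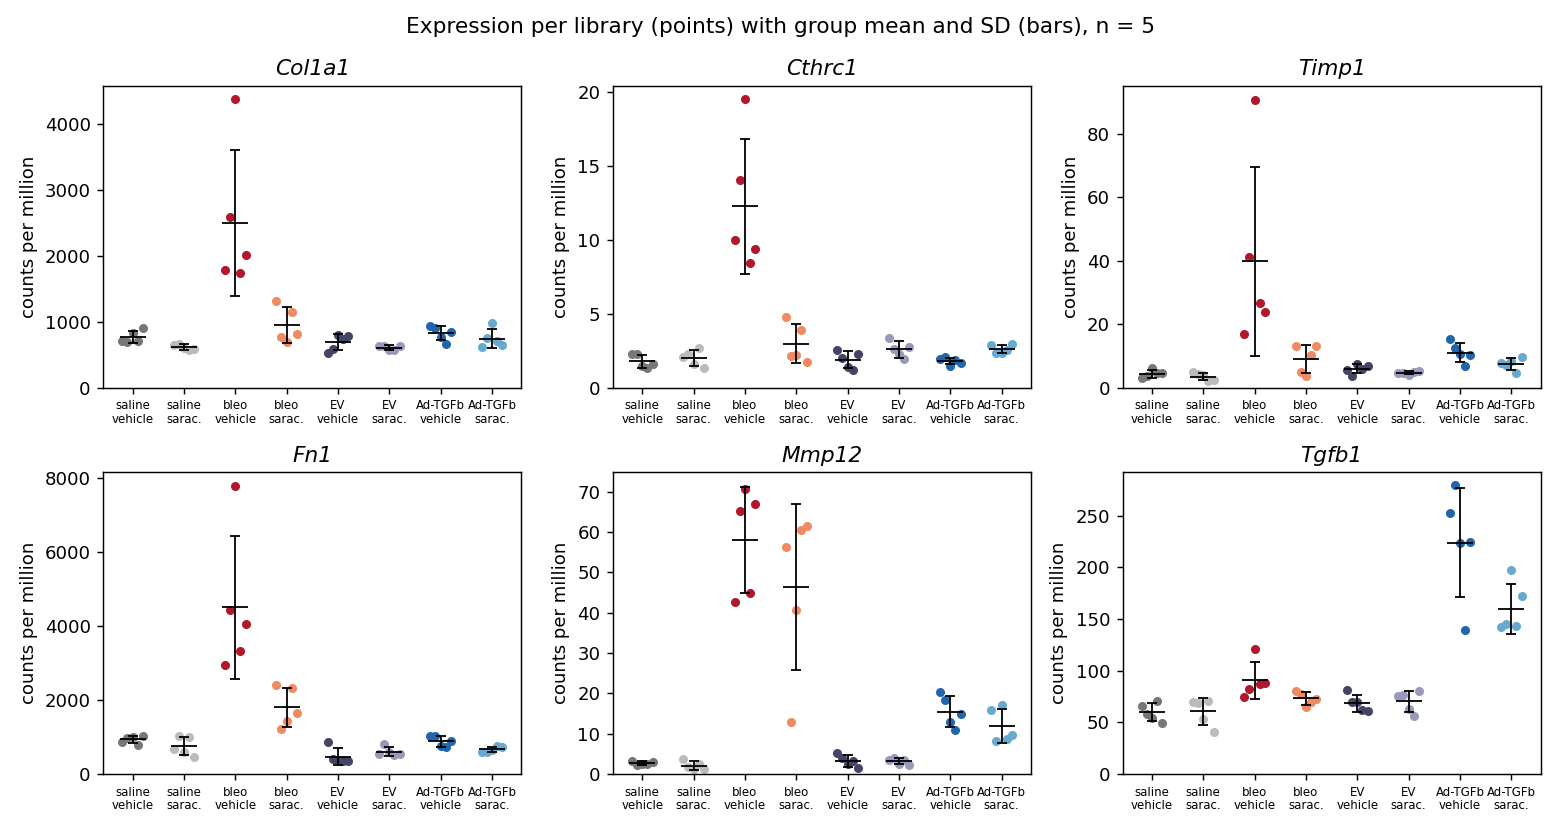
Counts per M of 6 genes in each of the 40 libraries, by group, on linear axes, with bars at the group mean and SD (n = 5). Col1a1, Cthrc1, Timp1, Fn1 and Mmp12 rose with bleomycin, and Tgfb1 rose more with Ad-TGFβ1 than with bleomycin.

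Bleomycin lungs given vehicle were compared with saline lungs given vehicle to find what injury did to lung transcripts. Most tested members of the lists of matrix proteases, tissue macrophages, cell cycle and transitional alveolar epithelium rose, and most of those of alveolar fibroblasts and ciliated cells fell. None of the list calls held with an estimated correlation, where the lowest adjusted p was 0.0776. Col1a1 rose from 766 ± 94.8 to 2505 ± 1108 CPM (mean ± SD, n = 5), a log2 fold change of 1.71 ± 0.22 (adjusted p = 8.5e-06). Cthrc1 rose by 2.77 ± 0.29, Timp1 by 3.19 ± 0.43, Fn1 by 2.27 ± 0.27, and Mmp12 by 4.43 ± 0.37, from 2.69 ± 0.496 to 58.1 ± 13.2 CPM. Col3a1 (1.06), the macrophage and matrix phosphoprotein gene Spp1 (2.96), Tgfb1 (0.60) and Src (0.24) also rose. The other 4 panel genes were not called, with log2 fold changes of 0.08 for the matrix gene Postn, -0.51 for smooth muscle actin Acta2, 0.31 for the surfactant gene Sftpc and 0.54 for the type 1 cell gene Ager. Ager was called at 0.740 without saline vehicle library 1 (edgeR adjusted p = 0.0428).

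Among 30 tested matrix proteases and inhibitors, 21 rose and 2 fell, or 23 and 4 adjusted over the list alone (camera adjusted p = 1.15e-10, and adjusted p = 0.182 with an estimated correlation). Of 20 genes of activated fibroblasts, 16 rose and 1 fell, the same counts adjusted over the list alone (camera adjusted p = 4.06e-11, and adjusted p = 0.182 with an estimated correlation). Examples were Lrrc15 (5.08 ± 0.76), the BMP antagonist Grem1 (3.46 ± 0.53), tenascin C gene Tnc (3.26 ± 0.34) and Cilp (3.00 ± 0.38). Collagens and their processing enzymes had 21 higher and 2 lower of 31, or 21 and 4 adjusted over the list alone, with Col11a1 at 5.67 and the prolyl hydroxylase gene P4ha3 at 2.56 (camera adjusted p = 1.69e-06, and adjusted p = 0.437 with an estimated correlation). In the list of TGF-beta pathway genes, 21 of 30 rose and 3 fell, also adjusted over the list alone, among the risers the activin chain gene Inhba (2.49 ± 0.40) and the latent TGF-beta binding protein gene Ltbp2 (1.75 ± 0.17) (camera adjusted p = 4.31e-07, and adjusted p = 0.234 with an estimated correlation). Alveolar fibroblast genes went the other way, with 11 of 15 lower and 1 higher, unchanged adjusted over the list alone (camera adjusted p = 1.5e-10, and adjusted p = 0.182 with an estimated correlation). The amino acid transporter gene Slc7a10 fell by 4.23, from 84.8 ± 19.3 to 4.61 ± 3.09 CPM, the methyltransferase gene Inmt fell by 2.16 and the receptor gene Fgfr4 fell by 2.05.

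Of 24 genes of monocyte-derived and tissue macrophages, 22 rose and none fell, with 22 adjusted over the list alone (camera adjusted p = 8.81e-22, and adjusted p = 0.0776 with an estimated correlation). They included the arginase gene Arg1 (3.87 ± 0.53), the lipid receptor gene Trem2 (3.51 ± 0.24) and Gpnmb (3.15 ± 0.27). Cell cycle genes rose in 32 of 33 cases and in 33 adjusted over the list alone, for example cyclin B1 gene Ccnb1 (2.63 ± 0.35) and the mitotic kinase gene Cdk1 (2.14 ± 0.30) (camera adjusted p = 1.76e-16, and adjusted p = 0.27 with an estimated correlation). In transitional alveolar epithelium, a state seen during repair, 17 of 19 genes rose and 18 did adjusted over the list alone (camera adjusted p = 3.34e-12, and adjusted p = 0.0776 with an estimated correlation), among them the claudin gene Cldn4 (2.82 ± 0.36) and the lipocalin gene Lcn2 (2.63 ± 0.26). Of 24 targets of p53 and senescence genes, 18 rose, and 19 adjusted over the list alone (camera adjusted p = 8.6e-09, and adjusted p = 0.0776 with an estimated correlation), with the cell cycle inhibitor gene Cdkn2a at 2.52 ± 0.43 and the receptor gene Eda2r at 1.61 ± 0.18. T cell genes rose in 16 of 20 cases, and in 16 adjusted over the list alone, including the checkpoint receptor gene Ctla4 (3.19 ± 0.50) and the regulatory T cell factor gene Foxp3 (2.87 ± 0.36) (camera adjusted p = 3.08e-06, and adjusted p = 0.313 with an estimated correlation).

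Markers of other cells in the lung piece moved with these groups. Ciliated cell genes fell in 15 of 18 cases, 16 adjusted over the list alone, for instance Hydin (-1.32) and Tppp3 (-1.19) (camera adjusted p = 4.7e-05, and adjusted p = 0.531 with an estimated correlation). The mean log2 CPM of the list differed by -0.994 ± 0.340 (exact permutation p = 0.0159 and adjusted p = 0.0476 over 6 tests). Striated muscle genes fell in 9 of 19 cases, also adjusted over the list alone, with the atrial peptide gene Nppa at -3.71 and the heart myosin gene Myh6 at -2.07 (camera adjusted p = 0.00115, and adjusted p = 0.53 with an estimated correlation). Capillary endothelial genes fell in 12 of 22 cases, or 13 adjusted over the list alone, such as Ednrb (-1.81) and Bmp6 (-1.64) (camera adjusted p = 0.000245, and adjusted p = 0.556 with an estimated correlation). Mitochondrially encoded genes fell in 10 of 11 cases, also adjusted over the list alone (camera adjusted p = 2.88e-05, and adjusted p = 0.335 with an estimated correlation), mt-Nd2 by -1.13 and mt-Nd4 by -0.94.

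In edgeR's test 7716 genes were called, of which 3888 were higher and 3828 lower. Among genes with non-overlapping groups, the largest rises were in the C-type lectin gene Chodl (7.03 ± 0.89), the Wnt antagonist gene Frzb (6.53 ± 0.85), the cartilage collagen gene Col10a1 (6.32 ± 0.84) and the thrombospondin gene Thbs4 (6.13 ± 0.71). The kininogen gene Kng2 (6.07) has a close paralog in Kng1, so reads of the pair are uncertain. Ankrd34b rose by 5.14. The largest falls were in the xenobiotic enzyme gene Cyp1a1 (-5.25 ± 1.10), in Slc7a10 and in the acetylcholinesterase collagen tail gene Colq (-3.76 ± 0.35), followed by Sost (-3.55), Asgr1 (-3.38), Tmem132d (-3.38), Slc5a12 (-3.30) and Fabp12 (-3.23). With the ciliated cell score as a covariate, chosen after the data were seen, 5003 genes were called, 3953 of them among the 7716.

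**Figure D2:**
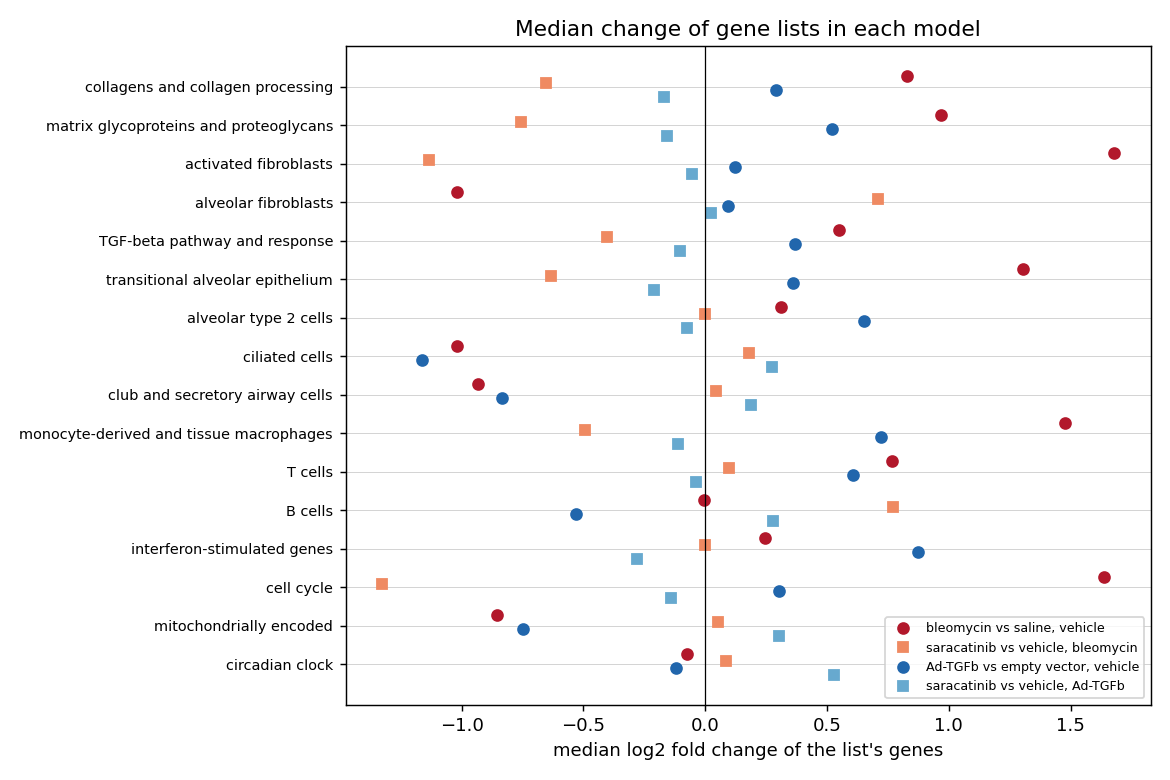
Median log2 fold change of the tested members of 16 gene lists in 4 comparisons, namely each injury in vehicle lungs and saracatinib in each injured lung. In bleomycin lungs the medians with saracatinib lie on the opposite side of 0 from those with injury for activated fibroblasts, collagens and cell cycle genes.

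Saracatinib was compared with vehicle in bleomycin lungs to find what the drug did to the injured lung. Most tested members of the lists of cell cycle, activated fibroblast and collagen genes fell, and most of those of alveolar fibroblasts rose. None of the list calls held with an estimated correlation, where the lowest adjusted p was 0.164. Col1a1 went from 2505 ± 1108 to 949.7 ± 269 CPM, a log2 fold change of -1.40 ± 0.22 (adjusted p = 0.00198), against 766 ± 94.8 CPM in saline vehicle lungs. Cthrc1 fell by 2.05 ± 0.28, Timp1 fell by 2.15 ± 0.40, Fn1 fell by 1.32 ± 0.26 and Spp1 fell by 1.18 ± 0.36. Col3a1 (-0.76) also fell. Of these, Spp1 was no longer called without any one of 4 libraries. The 7 other panel genes were not called, including Mmp12 at -0.33 ± 0.29 (adjusted p = 0.485), Tgfb1 at -0.31 ± 0.14 and Src at -0.08 ± 0.06. Postn was at -0.38, Acta2 at -0.25, Sftpc at 0.03 and Ager at 0.19.

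Cell cycle genes fell in 30 of 33 cases and in 31 adjusted over the list alone (camera adjusted p = 9.61e-28, and adjusted p = 0.164 with an estimated correlation), among them Ccnb1 (-1.85 ± 0.32), the spindle factor gene Tpx2 (-1.82 ± 0.28) and the topoisomerase gene Top2a (-1.58 ± 0.27). Of 20 activated fibroblast genes 15 fell, or 17 with 1 higher adjusted over the list alone (camera adjusted p = 1.73e-16, and adjusted p = 0.164 with an estimated correlation), such as Lrrc15 (-2.94 ± 0.59), Grem1 (-2.30 ± 0.48) and the follistatin gene Fst (-2.18 ± 0.37). Collagens and their enzymes fell in 22 of 31 cases, 23 adjusted over the list alone, with Col11a1 at -2.08 and P4ha3 at -1.98 (camera adjusted p = 5.93e-16, and adjusted p = 0.164 with an estimated correlation). Matrix glycoproteins had 21 lower and 3 higher of 34, or 23 and 4 adjusted over the list alone, with Thbs2 at -2.28 and Tnc at -1.86 (camera adjusted p = 4.57e-11, and adjusted p = 0.164 with an estimated correlation). In the TGF-beta list 13 of 30 genes fell and 1 rose, or 18 and 1 adjusted over the list alone, among them Inhba (-2.03) and Tgfbi (-1.10) (camera adjusted p = 8.27e-09, and adjusted p = 0.164 with an estimated correlation). Tissue macrophage genes fell in 10 of 24 cases, 15 adjusted over the list alone, including Arg1 (-2.67), the growth factor gene Igf1 (-1.53) and the complement gene C1qa (-1.05) (camera adjusted p = 1.88e-09, and adjusted p = 0.164 with an estimated correlation). Alveolar fibroblast genes rose in 9 of 15 cases, 11 adjusted over the list alone, with Slc7a10 at 2.41 ± 0.33, Inmt at 1.46 ± 0.27 and Tcf21 at 0.95 ± 0.20 (camera adjusted p = 5.7e-09, and adjusted p = 0.164 with an estimated correlation). B cell genes rose in 7 of 14 cases, 12 adjusted over the list alone, for example the B cell factor gene Pax5 (1.01) (camera adjusted p = 6.62e-08, and adjusted p = 0.33 with an estimated correlation).

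The list of Src family kinases and focal adhesion genes was not called in this comparison, with 2 higher and 3 lower of 24, the same adjusted over the list alone (camera adjusted p = 0.809). Ciliated cell genes were not called either, with a score difference of 0.252 ± 0.265 (exact permutation p = 0.389). In all, edgeR called 2643 genes, of which 1001 were higher and 1642 lower. The largest rises were in Slc7a10, Colq (2.40 ± 0.35), Tmem121b (2.16), the muscle genes Myom2 (1.62) and Mypn (1.57), the adrenergic receptor gene Adra1a (1.54), Col17a1 (1.53) and Fam71f2 (1.53). The largest falls were in the TNF family ligand gene Tnfsf18 (-2.84 ± 0.54), Arg1, Frzb (-2.41), Col10a1 (-2.36), Thbs4 (-2.34), the potassium channel gene Kcnt1 (-2.30), Grem1 and Thbs2. Bleomycin vehicle library 3 and saline saracatinib library 5 lay farthest from their groups on the first principal components, and 1661 genes were called without them, 1592 of them among the 2643. The count was 1326 without bleomycin saracatinib library 2, 1470 without its library 3, 1690 without bleomycin vehicle library 2 and 1339 without its library 3.

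Saracatinib in saline lungs was the control for what the drug does to uninjured lung. One gene was called of 18846, Adamtsl2, a matrix protein that binds fibrillin, which went from 202 ± 50.2 to 90.3 ± 11.7 CPM (-1.16 ± 0.16, adjusted p = 0.00841). Adamtsl2 was not called with only the compared groups in the fit (edgeR adjusted p = 0.0554) or with the clock score (edgeR adjusted p = 0.159), where 1 other gene was. None of the 14 panel genes passed the test, with Col1a1 at -0.32 ± 0.21 and Col3a1 at -0.38 ± 0.15. Genes of the circadian clock were not called over all genes, but 5 were higher and 4 lower adjusted over the list alone of 16. A clock score differed by 1.03 ± 0.244, with all 5 saracatinib libraries above all 5 vehicle libraries (exact permutation p = 0.00794 and adjusted p = 0.0159 over 6 tests). The score is the mean log2 CPM of the D-box and Rev-erb genes minus that of Arntl, Npas2, Clock and Nfil3. At an unadjusted p under 0.05 there were 1401 genes, DESeq2 called 52, limma voom 9, and edgeR 3 without the low-count filter and 16 with the ciliated score. Preset-correlation camera called 27 of 49 lists, of which 0 held with an estimated correlation, where the lowest adjusted p was 0.341, and 0 by fry. Leaving out a library gave 4 genes without saline saracatinib library 2, 0 without its library 3, 2 without saline vehicle library 1 and 3 without its library 5.

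The interaction asks whether saracatinib acted differently in bleomycin and in saline lungs. The Cthrc1 change with the drug in bleomycin lungs, -2.05, minus that in saline lungs, 0.17 ± 0.33 and not called, was -2.21 ± 0.43 (adjusted p = 0.0224), and the other 13 panel genes did not pass, with Col1a1 at -1.08 ± 0.30 (adjusted p = 0.078). Cthrc1 was no longer called without any one of 3 libraries, and Col1a1 was called without either of 2. Called genes with the most negative interaction also included the hyaluronan synthase gene Has2 (-3.14 ± 0.76), Fst (-2.48 ± 0.54), Cldn4 (-2.36 ± 0.50), the replication gene Gins2 (-2.28) and the pericyte gene Rgs5 (-2.22). The most positive were Ankrd63 (4.49 ± 0.98), Slc7a10 (3.15 ± 0.43), Colq (2.75), Adra1a (2.14) and the glutamate receptor gene Gria1 (2.13). Alveolar fibroblast genes were higher in 6 of 15 cases, 10 adjusted over the list alone, among them Fgfr4 (1.76) and Tcf21 (1.29) (camera adjusted p = 1.61e-17, and adjusted p = 0.125 with an estimated correlation). Cell cycle genes were lower in 3 of 33, namely Cdk1, Tpx2 and Kif23, and in 24 adjusted over the list alone (camera adjusted p = 2.86e-18, and adjusted p = 0.541 with an estimated correlation). The test called 199 genes, of which 115 were positive and 84 negative. DESeq2 called 838, limma voom 415, and edgeR 45 with Xist, 877 with the ciliated score, 90 with the clock score and 54 without the 2 farthest libraries. Leaving out a library gave 583, 39, 43 and 51 genes without bleomycin saracatinib libraries 1, 2, 3 and 5. It gave 435, 35 and 91 without bleomycin vehicle libraries 1, 2 and 3, and 61, 93, 58 and 76 without saline saracatinib libraries 1, 2, 3 and 5. In saline vehicle lungs it gave 100, 55, 67, 57 and 63 without libraries 1 to 5.

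Changes with saracatinib in bleomycin lungs were set against changes with bleomycin. Of the 7716 genes called with bleomycin, 7357 (95.3%) had a saracatinib change of the opposite sign. Of 2388 genes called in both, 1522 rose with bleomycin and fell with saracatinib and 865 did the reverse. Both effects use the bleomycin vehicle libraries with opposite sign, which alone pushes signs apart, and the share and counts expected from that were not computed here. The 2388 became 1264 without bleomycin saracatinib library 2 (835 and 428), 1356 without its library 3 (847 and 508), 1579 without bleomycin vehicle library 2 (1062 and 516) and 1257 without its library 3 (820 and 437). A single gene rose in both and 0 fell in both, by edgeR's test at the same threshold, which also gave 1 and 0 with DESeq2's size factors, and DESeq2's own test gave 4 and 0. Pearson's r across the 18846 genes, which are not independent replicates, was -0.773 and Spearman's rho -0.782. For the shared libraries alone, 20 simulations of unchanged groups gave a mean r of -0.494 and a covariance of -0.0225. The values observed on group means were -0.817 and -0.207. When those libraries were split so that no library served both effects, r averaged -0.664 over 20 splits and ran from -0.745 to -0.565.

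Ad-TGFβ1 lungs given vehicle were compared with empty vector lungs given vehicle to find what the delivered cytokine did. Tgfb1 rose from 68.6 ± 8.12 to 224 ± 52.5 CPM (1.71 ± 0.15, adjusted p = 4.73e-06), and whether reads came from the vector or the mouse gene cannot be read from gene counts. Most tested members of the lists of interferon-stimulated, alveolar type 2 and basement membrane genes rose, and most of those of ciliated, club and contractile genes fell. No list call held with an estimated correlation, where the lowest adjusted p was 0.105. Mmp12 rose by 2.24 ± 0.28, Fn1 by 0.93 ± 0.21, Timp1 by 0.91 ± 0.21, Sftpc by 0.76 ± 0.18, Postn by 0.72 ± 0.21 and Col3a1 by 0.47 ± 0.11, while Acta2 fell by 0.93 ± 0.25. Col1a1 was not called (0.26 ± 0.13, adjusted p = 0.15), nor were Cthrc1 (-0.06 ± 0.20), Spp1 (0.58), Ager (0.46) and Src (0.07). Spp1 was 75.9 CPM in empty vector vehicle library 1 and 9.71 to 31.3 CPM in the other 4, and without that library it rose by 1.29 (edgeR adjusted p = 0.000984). Ager, at 912 CPM there and 367 to 557 in the others, then rose by 0.71 (edgeR adjusted p = 0.000251). Postn was no longer called without library 3, 4 or 5 of that group or without Ad-TGFβ1 vehicle library 1.

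Interferon-stimulated genes rose in 28 of 34 cases and in 32 adjusted over the list alone (camera adjusted p = 1.74e-17, and adjusted p = 0.158 with an estimated correlation), among them the chemokine genes Cxcl9 (2.90 ± 0.47) and Cxcl10 (2.31 ± 0.45) and the GTPase gene Iigp1 (1.77 ± 0.34). In the TGF-beta list 15 of 30 rose, also adjusted over the list alone, such as Ltbp2 (1.67 ± 0.15), the TGF-beta activating integrin gene Itgb6 (1.13 ± 0.14) and the feedback gene Pmepa1 (1.08 ± 0.11) (camera adjusted p = 2.25e-13, and adjusted p = 0.105 with an estimated correlation). Matrix glycoproteins had 16 higher and 2 lower of 33, or 17 and 3 adjusted over the list alone, with elastin gene Eln at 1.63 and Ccn4 at 1.67 (camera adjusted p = 4.01e-12, and adjusted p = 0.105 with an estimated correlation). Basement membrane genes had 17 higher and 1 lower of 21, or 17 and 2 adjusted over the list alone, with laminin genes Lama1 (1.57) and Lamb3 (1.25) (camera adjusted p = 2.46e-09, and adjusted p = 0.114 with an estimated correlation). Alveolar type 2 genes rose in 16 of 20, also adjusted over the list alone, including the protease gene Napsa (1.05) and Lamp3 (0.99) (camera adjusted p = 4.24e-12, and adjusted p = 0.114 with an estimated correlation). Collagens and their enzymes had 15 higher and 2 lower of 30, or 16 and 2 adjusted over the list alone, with the crosslinking enzyme gene Lox at 1.19 and P4ha3 at 1.68 (camera adjusted p = 1.3e-07, and adjusted p = 0.114 with an estimated correlation). Cytotoxic lymphocyte genes rose in 8 of 13, 9 adjusted over the list alone, with interferon gamma gene Ifng at 3.14 and granzyme gene Gzmb at 1.48 (camera adjusted p = 1.17e-06, and adjusted p = 0.158 with an estimated correlation). In the cell cycle list 2 of 33 rose, E2f1 (0.39) and Mcm4 (0.33), also adjusted over the list alone (camera adjusted p = 0.000255, and adjusted p = 0.555 with an estimated correlation).

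Ciliated cell genes fell in 18 of 18 cases, also adjusted over the list alone, with Cfap126 among them and Deup1 at -1.37 ± 0.26 (camera adjusted p = 8.91e-16, and adjusted p = 0.119 with an estimated correlation). The ciliated score differed by -1.08 ± 0.268 (exact permutation p = 0.0159 and adjusted p = 0.0476 over 6 tests). Club cell genes fell in 12 of 18, also adjusted over the list alone, among them the cytochrome gene Cyp2f2 (-1.06 ± 0.22) and the immunoglobulin receptor gene Pigr (-1.05 ± 0.19) (camera adjusted p = 1.1e-06, and adjusted p = 0.116 with an estimated correlation). Contractile genes fell in 11 of 17, 12 adjusted over the list alone, among them Cnn1 and Myh11 (-0.96) (camera adjusted p = 0.000496, and adjusted p = 0.401 with an estimated correlation). Mitochondrially encoded genes fell in 8 of 10, 9 adjusted over the list alone, with mt-Nd2 at -0.92 (camera adjusted p = 2.25e-08, and adjusted p = 0.119 with an estimated correlation). Called genes numbered 4865 in edgeR, of which 2173 were higher and 2692 lower. The largest rises with non-overlapping groups were in Btnl6 (4.05 ± 0.59), the itaconate enzyme gene Acod1 (3.67 ± 0.67), Kcng1 (3.03), Cxcl9, Lrrn1 (2.70), Mmp13 (2.61), Nrk (2.51) and Ccl3 (2.40). Btnl6 belongs to a family of near copies, so its reads are uncertain. The largest falls were in the multiciliation gene Ccno (-1.69 ± 0.38), Aspg (-1.65), Espnl (-1.64), Fer1l4 (-1.57), Barhl1, Cfap126, Armh1 (-1.49) and Snord55 (-1.45).

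With the ciliated score as a covariate, chosen after the data were seen, 6 genes were called between Ad-TGFβ1 and empty vector, and 11 of the named genes turned sign, among them Postn, at -0.135 with an adjusted p of 0.902, and Cyp2f2, at 0.074. The median change went from 0.87 to 0.54 for interferon-stimulated genes, from 0.72 to 0.47 for tissue macrophage genes, from 0.37 to 0.17 for TGF-beta genes, from 0.65 to 0.23 for alveolar type 2 genes and from 0.38 to 0.13 for basement membrane genes. Empty vector vehicle libraries 5 and 1 lay farthest from their group, and 5905 genes were called without them.

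Saracatinib in Ad-TGFβ1 lungs changed 17 genes past the threshold, of which 7 were in the list of the circadian clock. Rises came in the clock output transcription factor genes Dbp (1.92 ± 0.31, adjusted p = 0.0238), Hlf (1.02 ± 0.17) and Tef (0.93 ± 0.15), in the period gene Per3 (1.07 ± 0.19) and in the Rev-erb gene Nr1d2 (0.80 ± 0.15). The core clock activator gene Arntl fell by 1.02 ± 0.18 and Nfil3, a repressor of D-box genes, fell by 1.05 ± 0.20. In that list 5 genes rose and 2 fell of 16, or 9 and 4 adjusted over the list alone, and its camera call held with an estimated correlation (camera adjusted p = 3.81e-07, adjusted p = 0.0242 with an estimated correlation). The clock score differed by 1.99 ± 0.285, with all 5 saracatinib libraries above all 5 vehicle libraries (exact permutation p = 0.00794, the smallest such a test can give, and adjusted p = 0.0159 over 6 tests). No panel gene passed, with Col1a1 at -0.15 ± 0.13, Fn1 at -0.41 ± 0.21, Timp1 at -0.56 ± 0.20, Cthrc1 at 0.53 ± 0.19 and Tgfb1 at -0.49 ± 0.15 (adjusted p = 0.361).

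Outside the clock, the named genes that rose were Sord (0.57), Snhg11 (0.49) and Gpr155 (0.43). Those that fell were the matrix gene Spon2 (-1.38 ± 0.21), Ccnjl (-1.29), the metalloproteinase gene Adamts9 (-1.08 ± 0.18), Rasl11a (-0.92) and Bcl3 (-0.82). Of the 17 genes 9 were higher and 8 lower, with 1649 at an unadjusted p under 0.05. DESeq2 called 51, limma voom 101, and edgeR 7 with Xist, 4 with the ciliated score and 0 with the clock score as a covariate, where Per3 stood at -0.058, Nr1d2 at -0.069 and Arntl at 0.048. These 3 genes are part of that score, so values near 0 follow from its construction. The score also separated the saracatinib from the vehicle libraries, so as a covariate it takes up the drug contrast. The count of 0 therefore cannot be laid to clock genes alone. Leaving out a library gave 8, 0 and 0 genes without Ad-TGFβ1 saracatinib libraries 2, 4 and 5, and 11, 0, 3, 10 and 4 without Ad-TGFβ1 vehicle libraries 1 to 5.

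**Figure D3:**
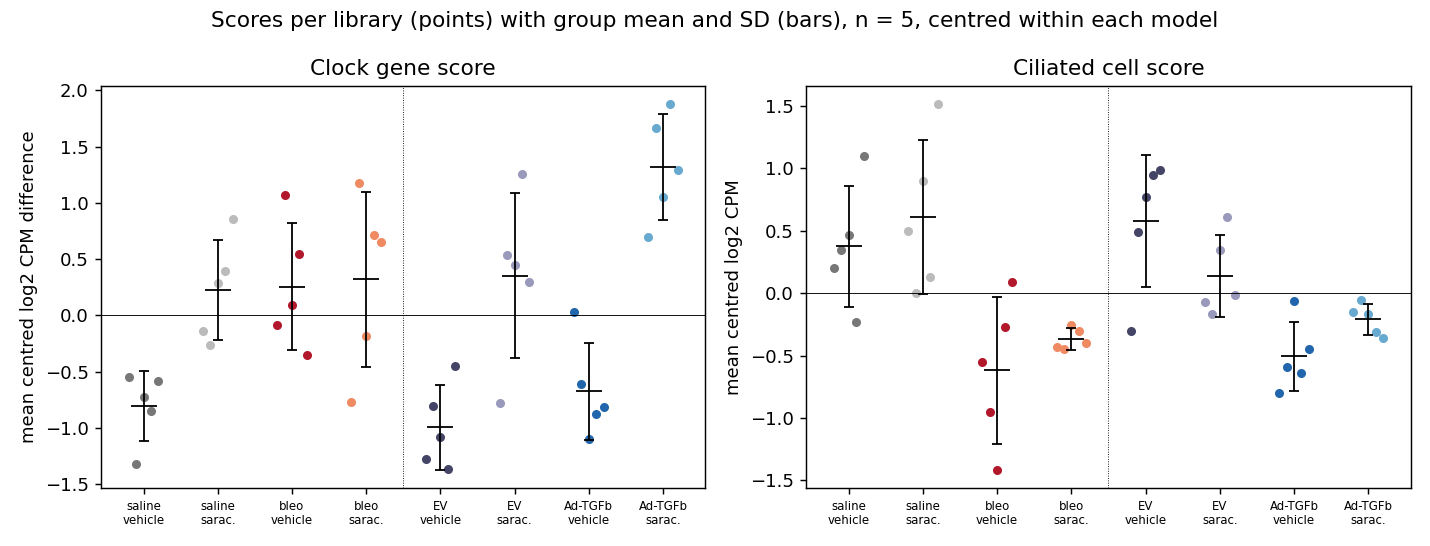
The clock score and the ciliated cell score of each library, in log2 CPM centred within its model, by group, with bars at the group mean and SD (n = 5). In the Ad-TGFβ1 model all 5 saracatinib libraries have a higher clock score than all 5 vehicle libraries of the injured lungs.

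Saracatinib in empty vector lungs changed 1 gene past the threshold, the vasodilator peptide gene Adm, from 6.64 ± 1.12 to 2.94 ± 0.7 CPM (-1.17 ± 0.18, adjusted p = 0.0417). Adm was not called with only the compared groups in the fit (edgeR adjusted p = 0.742), without the low-count filter (0.0678), with the ciliated score (0.229) or with the clock score (0.676). No panel gene passed, with Fn1 at 0.39 ± 0.21 and Acta2 at -0.44 ± 0.25. Without empty vector vehicle library 1, where Fn1 was 871 CPM against 341 to 398, Fn1 rose by 0.756 (edgeR adjusted p = 0.0127), Spp1 by 0.961 (0.0437), Sftpc by 0.525 (0.0334) and Ager by 0.467 (0.0390). The clock score was higher by 1.35 ± 0.368 with the drug (exact permutation p = 0.0159 and adjusted p = 0.0238 over 6 tests). There were 2084 genes at an unadjusted p under 0.05, DESeq2 called 7 and limma voom 1. Camera called 22 lists, of which 0 held with an estimated correlation (lowest adjusted p = 0.736) and 0 by fry. Without the 2 farthest libraries 130 genes were called, and without empty vector vehicle library 1 alone 1112, against 4 without its library 2 and 0 without any one of the other 8.

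The interaction of saracatinib with Ad-TGFβ1 called 0 of 18834 genes in edgeR. There were 1933 genes at an unadjusted p under 0.05, DESeq2 called 1 and limma voom 413. Tgfb1 stood at -0.53 ± 0.21 (adjusted p = 0.481), Fn1 at -0.80 ± 0.30 and Col1a1 at 0.02 ± 0.18. Fn1 was at -1.165 without empty vector vehicle library 1 (edgeR adjusted p = 0.00655). Of 18 ciliated cell genes, 13 were positive adjusted over the list alone and 0 over all genes (camera adjusted p = 6.84e-12, and adjusted p = 0.319 with an estimated correlation). Without the 2 farthest libraries 254 genes were called, and without empty vector vehicle library 1 alone 1190, against 1 without empty vector saracatinib library 4.

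Set against the Ad-TGFβ1 effect, 87.9% of the 4865 genes called with injury had a saracatinib change of the opposite sign, and 3 genes were called in both. The Ad-TGFβ1 vehicle libraries serve both effects with opposite sign, so no share expected without a drug effect is given. That overlap was 10 without empty vector vehicle library 1, 1 without its library 3 or 4, 1 without Ad-TGFβ1 saracatinib library 1 and 0 without its library 4 or 5. It was 0 without Ad-TGFβ1 vehicle library 2 and 1 without its library 3 or 5. Pearson's r across 18834 genes was -0.508 and Spearman's rho -0.565. On group means r was -0.555 with a covariance of -0.0570, against a mean r of -0.491, a lowest r of -0.517 and a covariance of -0.0237 in 20 simulations of unchanged groups. With no library shared, r averaged -0.304 over 20 splits and ran from -0.457 to -0.150. With the clock score as a covariate r was -0.00588. That score separated the saracatinib from the vehicle libraries in Ad-TGFβ1 lungs, so as a covariate it also takes up the drug contrast. This value therefore cannot show that clock genes account for r.

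The injury effects of the 2 models were then compared gene by gene, in a fit of all 40 libraries and 19529 genes. By camera at the preset correlation, the bleomycin effect was the higher in activated fibroblast, matrix protease, tissue macrophage, cell cycle and p53 genes and the lower in capillary endothelium, striated muscle, alveolar fibroblast, interferon and cytotoxic lymphocyte genes, among others, and none of the list calls held with an estimated correlation. The bleomycin effect exceeded the Ad-TGFβ1 effect by 2.84 ± 0.37 for Cthrc1 (adjusted p = 2.87e-06), 2.39 ± 0.55 for Spp1, 2.29 ± 0.49 for Timp1, 2.20 ± 0.48 for Mmp12 and 1.46 ± 0.26 for Col1a1. It did so too for Fn1 (1.35) and Col3a1 (0.59). Without empty vector vehicle library 1 the Spp1 difference was 1.65 (edgeR adjusted p = 0.0147), Postn differed by -0.974 (0.00416) and Sftpc by -0.714 (0.0463). Col3a1 was no longer called without any one of 9 libraries. Tgfb1 differed the other way (-1.10 ± 0.22), and Postn (-0.63), Acta2 (0.43), Sftpc (-0.44), Ager (0.09) and Src (0.18) did not pass. Outside the panel the largest positive differences were in Kng2 (5.95 ± 0.75), Kng1 (5.52 ± 1.89), Thbs4 (5.41 ± 1.10) and the Wnt antagonist gene Dkk2 (5.21 ± 0.58). The largest negative ones were in Cyp1a1 (-5.11 ± 1.29), Slc7a10 (-4.05 ± 0.42), Slc5a12 (-3.46), Bcan (-3.46) and Tmem132d (-3.46).

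Alveolar fibroblast genes differed downward in 9 of 15 cases, 11 adjusted over the list alone, with Tcf21 at -1.65 (camera adjusted p = 5.6e-14, and adjusted p = 0.0797 with an estimated correlation). Activated fibroblast genes differed upward in 13 of 20, or 15 with 1 downward adjusted over the list alone, with Grem1 at 3.72 (camera adjusted p = 7.82e-10, and adjusted p = 0.14 with an estimated correlation). Matrix proteases and inhibitors did so in 13 of 30, or 14 with 1 downward adjusted over the list alone (camera adjusted p = 2.38e-06, and adjusted p = 0.265 with an estimated correlation). Matrix glycoproteins were not called as a list, with 10 upward and 6 downward of 34, or 14 and 6 adjusted over the list alone (camera adjusted p = 0.525). Cell cycle genes differed upward in 21 of 33, 27 adjusted over the list alone, with Ccnb1 at 2.12 (camera adjusted p = 2.94e-10, and adjusted p = 0.587 with an estimated correlation). So did p53 targets in 11 of 24, 16 adjusted over the list alone, with Eda2r at 1.40 (camera adjusted p = 1.41e-07, and adjusted p = 0.0797 with an estimated correlation). Cytotoxic lymphocyte genes differed downward in 7 of 13, 12 adjusted over the list alone, with Ifng at -4.77 and Gzmb at -2.30 (camera adjusted p = 1.73e-08, and adjusted p = 0.164 with an estimated correlation). Capillary endothelium genes did so in 10 of 22, 15 adjusted over the list alone, with Hpgd at -1.86 (camera adjusted p = 5.98e-10, and adjusted p = 0.386 with an estimated correlation). Tissue macrophage genes differed upward in 13 of 24, 16 adjusted over the list alone, with Arg1 at 4.33 (camera adjusted p = 5.98e-10, and adjusted p = 0.14 with an estimated correlation). The downward call of striated muscle genes held 0 called genes of 20, 0 adjusted over the list alone (camera adjusted p = 0.0188, and adjusted p = 0.975 with an estimated correlation). Interferon-stimulated genes differed downward in 10 of 34, 11 adjusted over the list alone, with Gbp2 at -1.98 (camera adjusted p = 9.02e-07, and adjusted p = 0.793 with an estimated correlation). The test called 2951 genes, of which 1687 were positive and 1264 negative, and limma voom called 4756. Among the 18386 genes tested in both models, 7547 were called with bleomycin, 4792 with Ad-TGFβ1 and 2698 with both. Of these, 1178 rose in both models, where independence would give 438, and 1368 fell in both, where it would give 545, while 62 rose with bleomycin and fell with Ad-TGFβ1 and 90 did the reverse. The last counts were 134 and 301 without empty vector vehicle library 1, while the 62 became 33 and 40 without its libraries 4 and 5, and the 90 became 59 without its library 3 and 54 without Ad-TGFβ1 vehicle library 1. No library served both effects, and Pearson's r across genes was 0.487 with Spearman's rho 0.497. Without the low-count filter r was 0.172. With the ciliated score as a covariate 4887 genes were called with bleomycin, 5 with Ad-TGFβ1 and 3 with both, and r was 0.360. That score differed by -0.994 ± 0.340 with bleomycin and by -1.08 ± 0.268 with Ad-TGFβ1. The shared calls therefore cannot be told apart from a change in airway share common to both models. Genes also move together, so the counts under independence are not a test.

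The saracatinib effects in injured lungs were compared the same way. The change with the drug in bleomycin lungs minus that in Ad-TGFβ1 lungs was -2.58 ± 0.35 for Cthrc1 (adjusted p = 0.000145) and -1.24 ± 0.26 for Col1a1. Cthrc1 fell in bleomycin lungs and was not called in Ad-TGFβ1 lungs, at 0.53. Neither Cthrc1 nor Col1a1 was called with Ad-TGFβ1 itself, so there was no called rise for the drug to lower. Their differences therefore cannot be told apart from the unequal injury of the models. The other 12 panel genes did not pass, with Timp1 at -1.58 ± 0.47 (adjusted p = 0.0625) and Fn1 at -0.91 ± 0.35. Timp1 was called without any one of 4 libraries, and Col3a1 without 1. The largest positive differences were in Slc7a10 (2.35 ± 0.42), Colq (2.22 ± 0.46), the retinol enzyme gene Lrat (2.00), Gabrr2 (1.94) and the clock gene Npas2 (1.93 ± 0.37). Beside Cthrc1, the largest negative ones were in Kcnt1 (-2.67 ± 0.65), Thbs2 (-2.52 ± 0.53), Arg1 (-2.45) and Etv4 (-2.41). Activated fibroblast genes differed downward in 8 of 20 cases, 14 adjusted over the list alone, including Fst (-2.22) and Inhba (-2.01) (camera adjusted p = 1.15e-15, and adjusted p = 0.0741 with an estimated correlation). Collagens and their enzymes did so in 10 of 31, 16 adjusted over the list alone, such as Loxl2 (-1.22) (camera adjusted p = 3.51e-10, and adjusted p = 0.413 with an estimated correlation). Cell cycle genes did so in 10 of 33, 25 adjusted over the list alone, such as Tpx2 (-1.71) (camera adjusted p = 3.37e-19, and adjusted p = 0.413 with an estimated correlation).

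In that test 481 genes were called, of which 205 were positive and 276 negative. Of 2591 and 17 genes called with saracatinib in the 2 models, 4 were shared, 1 for each combination of directions. The 4 became 2 without bleomycin saracatinib library 2 or 3 or bleomycin vehicle library 5. Leaving out Ad-TGFβ1 saracatinib libraries 2, 4 and 5 gave 1, 0 and 0, and Ad-TGFβ1 vehicle libraries 1 to 5 gave 1, 0, 0, 2 and 1. Pearson's r across 18386 genes was 0.215 with Spearman's rho 0.289. The value of r was 0.0217 without the low-count filter and 0.0612 with the clock score. In Ad-TGFβ1 lungs that score separated the saracatinib from the vehicle libraries, so as a covariate it also takes up the drug contrast. DESeq2 called 766 genes, and edgeR 219 without the low-count filter, 285 without the 2 farthest libraries of each model, 1180 with the ciliated score and 37 with the clock score. Leaving out a library gave 803, 148, 161 and 257 genes without bleomycin saracatinib libraries 1, 2, 3 and 5. It gave 743, 182 and 106 without bleomycin vehicle libraries 1, 2 and 3. In the other model it gave 225, 192 and 310 without Ad-TGFβ1 saracatinib libraries 1, 3 and 5, and 254, 231 and 228 without Ad-TGFβ1 vehicle libraries 1, 3 and 4.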

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

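All tests of the 3 patterns below were chosen after the result was seen, and the regrouping test of the bleomycin effect and the restricted count of regroupings were written after theirs. For the other 9 comparisons the regrouping test was written before. The first tests of the airway pattern were replaced after they had been seen. In them 10 of 16 other cell type lists lay apart from a common change, and 4327 of the 4865 genes were called again without the 2 farthest libraries.

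Values that stand apart came from 160 group tests of 5 libraries, where about 1 in 20 groups, or 8, would give one by chance, and 9 did. Fn1 was 871 CPM in empty vector vehicle library 1, against 341 to 398 in the others, and 818 in empty vector saracatinib library 2, against 526 to 595. Tgfb1 was 121 CPM in bleomycin vehicle library 3, against 74.8 to 88.2. Sftpc was 2350.4 CPM in Ad-TGFβ1 saracatinib library 2, against 2907 to 3112, and Src was 99.0 CPM in empty vector vehicle library 5, against 79.7 to 84.5. Total counts were 13.9 M in bleomycin saracatinib library 2, against 12.7 to 13.0, and 16.0 M in empty vector saracatinib library 1, against 9.86 to 11.3. Mitochondrial genes took 0.995% in bleomycin vehicle library 5, against 0.720 to 0.776%, and the top gene took 3.74% in saline vehicle library 5, against 2.45 to 2.71%.

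Effects differed between kinds of lung in 199 genes for saracatinib by bleomycin, among them Cthrc1 at -2.21. The injury effect differed between models in 2951 genes, with Cthrc1 at 2.84, Spp1 at 2.39, Timp1 at 2.29, Mmp12 at 2.20, Col1a1 at 1.46, Fn1 at 1.35, Col3a1 at 0.59 and Tgfb1 at -1.10. The saracatinib effect differed in 481 genes, with Cthrc1 at -2.58 and Col1a1 at -1.24.

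Regrouping the libraries, with the true grouping among the 100, tested whether as many called genes arise by chance. No share below 1 in 100 can be reached, and the shares were not adjusted over the comparisons. Chance was made unlikely for bleomycin, where its 7716 genes were reached in 1 of 100 groupings and the highest other gave 639. The same held for saracatinib in bleomycin lungs, 2643 in 1 with 1447 the highest other. Saracatinib in Ad-TGFβ1 lungs reached its 17 in 1 with 0 the highest other, which made chance unlikely too. Its count was 0 without saracatinib library 4 or 5 or vehicle library 2. For Ad-TGFβ1, the 4865 genes were reached in 2, which also made chance unlikely. There the highest other called 5672 after exchanging empty vector vehicle library 1 and Ad-TGFβ1 vehicle library 3. Chance was not excluded for saracatinib in saline lungs, whose 1 gene was reached in 6 with 1014 the highest other, nor in empty vector lungs, 1 in 12 with 2556. The 2556 came from the true grouping with its sign turned and only saracatinib library 3 and vehicle library 1 exchanged. It therefore held most of the drug contrast. Groupings that exchanged 2 or 3 libraries per group were counted separately after these were seen. The highest of them called 1014 genes in saline and 2094 in empty vector lungs. Those counts point to a structure of the samples that is not the treatment.

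For effects that differ between kinds of lung, some groupings keep a real effect. The interaction with bleomycin reached its 199 in 2 groupings, and the highest other, 307, exchanged all bleomycin saracatinib and vehicle labels and so held the drug effect with its sign turned. The difference in injury effect reached its 2951 in 5, and the highest other, 3760, exchanged all bleomycin and saline labels, so this count cannot decide on chance. The difference in saracatinib effect reached its 481 in 2, the highest other 975, with 1 library exchanged in each bleomycin group and 3 in each Ad-TGFβ1 group. A count restricted to groupings with 2 or 3 libraries exchanged in every arm was added after these were seen. It held 62, 57 and 57 groupings, of which 0 were as large, and their highest counts were 8, 23 and 2. Such groupings stand for no effect in either arm, and not for equal effects. For the interaction with Ad-TGFβ1, which called 0, all 100 were as large and the highest other was 5.

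Clock genes such as Dbp, Per3 and Arntl differed between saracatinib and vehicle in Ad-TGFβ1 lungs, and the clock score differed in all pairs but the bleomycin one, at 0.0630 ± 0.429 (exact permutation p = 0.881). It also differed between bleomycin and saline lungs given vehicle, by 1.06 ± 0.287 (exact permutation p = 0.00794), so the shift was not confined to the saracatinib arms. Collection at another time of day remains possible. In the Ad-TGFβ1 pair 10 of 10 clock genes moved with their phase, against 7 in the bleomycin, 10 in the saline and 9 in the empty vector pair. The 10 were chosen after the calls in the Ad-TGFβ1 pair were seen, and most were among those calls. Their count there could hardly come out otherwise, and a drug effect on the clock could give it too, so it cannot decide. The labels give no times and the question stays open. The clock score difference was not alike in all 4 pairs, as that of the Ad-TGFβ1 pair exceeded that of the bleomycin pair by 1.93 ± 0.515. These were the largest and the smallest of the 4, and the bleomycin vehicle group was itself shifted. With collection times unknown, an equal drug effect in all pairs cannot be excluded.

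Genes called with Ad-TGFβ1 went with a fall of ciliated cell genes such as Ccno. A smaller share of airway as the only cause would move alveolar markers alike, and alveolar type 2 markers changed by 0.563 ± 0.139 more than alveolar fibroblast markers. That error was taken across marker genes and not across mice, so it cannot exclude this cause. As part of the cause a smaller share of airway stays open too. The median size of the called changes went from 0.515 to 0.101 with the ciliated score in the fit, while the score itself differs between the groups. A swap of empty vector vehicle library 1 and Ad-TGFβ1 vehicle library 3 was excluded by Tgfb1, at 81.15 CPM in the first and 223 in the second.

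Saracatinib changes in genes such as Col1a1 and Cthrc1 ran opposite to bleomycin changes. Shared vehicle libraries were not the only source, since r was -0.664 with none shared. A single library with strong injury was not either, as r was -0.605 without bleomycin vehicle library 3. Activated fibroblast genes moved back by 74.3% and tissue macrophage genes by 40.1%, a difference of 34.2 ± 7.89 percentage points. Splits of the vehicle libraries gave overlapping ranges, 42.7 to 128% for activated fibroblast genes and 28.1 to 55.4% for tissue macrophage genes. These lists were picked from those measured, and the parts are ratios of log changes. They therefore cannot exclude injury that was milder by the same part in all groups of genes. Milder injury of an even or uneven kind may remain, as no lung was measured before treatment.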

How the results depend on the processing

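Fits without the 2 farthest libraries of each model, with the genes of the shorter table, and with the ciliated or clock score were chosen after the result was seen, and the others before the data were examined. Where a result changed, the cause was not tested. The clock score differed between saracatinib and vehicle in all pairs but the bleomycin one, so as a covariate it also takes up the drug contrast. No paired analysis was possible because the titles carry animal numbers and nothing that joins animals across groups.

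For bleomycin in vehicle lungs the 7716 genes became 5003 with the ciliated score. Saracatinib in bleomycin lungs went from 2643 genes to 1661 without the farthest libraries, and to between 1326 and 2985 on leaving out 1 library. In saline lungs the drug's 1 gene became 3 without the low-count filter, 52 in DESeq2, 9 in limma voom, 3 without the farthest libraries, 4 with the genes of the shorter table and 16 with the ciliated score, and between 0 and 4 on leaving out a library. The interaction with bleomycin went from 199 to 838 in DESeq2, 415 in limma voom, 45 with Xist, 54 without the farthest libraries, 877 with the ciliated score and 90 with the clock score, and ran from 35 to 583 on leaving out a library.

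Ad-TGFβ1 in vehicle lungs went from 4865 genes to 6 with the ciliated score. The 17 genes with saracatinib in Ad-TGFβ1 lungs became 51 in DESeq2, 101 in limma voom, 7 with Xist, 4 with the ciliated score and 0 with the clock score, and between 0 and 14 on leaving out a library. In empty vector lungs the drug's 1 gene became 0 without the low-count filter, 7 in DESeq2, 130 without the farthest libraries, 0 with the ciliated score and 0 with only the compared groups, and between 0 and 1112 on leaving out a library. The interaction with Ad-TGFβ1 went from 0 to 1 in DESeq2, 413 in limma voom and 254 without the farthest libraries, and between 0 and 1190 on leaving out a library.

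The difference in injury effect went from 2951 genes to 4756 in limma voom. The difference in saracatinib effect went from 481 to 219 without the low-count filter, 766 in DESeq2, 285 without the farthest libraries, 1180 with the ciliated score and 37 with the clock score, and ran from 106 to 803 on leaving out a library.

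With an estimated correlation, camera called 0 lists in 9 comparisons and 1, the circadian clock, for saracatinib in Ad-TGFβ1 lungs. By fry there were 0 for saracatinib in saline lungs, 2 for the interaction with bleomycin, 2 for saracatinib in Ad-TGFβ1 lungs, 0 in empty vector lungs, 0 for the interaction with Ad-TGFβ1 and 1 for the difference in saracatinib effect. For the difference in injury effect fry called several lists, such as p53 targets (fry adjusted p = 1.70e-05) and alveolar fibroblasts (5.19e-05). It did not call collagens (0.216) or interferon-stimulated genes (0.104) there. Fry counts of the remaining comparisons are not given here. Saracatinib in Ad-TGFβ1 lungs had 13 lists with the clock score, and with the ciliated score there were 11 in empty vector lungs and 7 for the interaction with Ad-TGFβ1.

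Of 8110 values of named genes on leaving out a library, called or not, 7173 kept their side of the threshold, 920 lost their call, 17 gained one and 0 turned. Of 614 values 511 were called in the main fits, and only those could lose a call. With the ciliated score 152 did, with the clock score 76, without the farthest libraries 68 and with Xist 48. The count was 38 without the low-count filter, 22 with limma voom and 3 with DESeq2's size factors. Values that turned direction, 11 with the ciliated score and 3 with the clock score, are counted apart. With only the compared groups 52 of 555 lost it, and with DESeq2 0 of 612. Directions turned in a few cases under other settings. With the ciliated score, capillary genes turned for Ad-TGFβ1 (camera adjusted p = 5.57e-12) and for its interaction with saracatinib (camera adjusted p = 0.00221), and interferon-stimulated genes turned for saracatinib in Ad-TGFβ1 lungs with the clock score (camera adjusted p = 0.000929). For Ad-TGFβ1 with the ciliated score, Postn was at -0.135, Cckar at 0.385, Cyp2f2 at 0.074, Sema3c at -0.182, Calcrl at -0.232, Scd1 at -0.099, Dnajc3 at -0.018, Sgk1 at -0.244, Gsta2 at 0.436, Nqo1 at 0.192 and Gsta4 at 0.004, none of them called. For saracatinib in Ad-TGFβ1 lungs with the clock score, Per3 was at -0.058, Nr1d2 at -0.069 and Arntl at 0.048, which follows from these genes being part of that score.

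Pearson's r of the injury effects went from 0.487 to 0.172 without the low-count filter and 0.360 with the ciliated score. For the saracatinib effects r went from 0.215 to 0.0217 without the filter and 0.0612 with the clock score. Between saracatinib and injury, r went from -0.773 to -0.559 without the filter in the bleomycin model, and from -0.508 to -0.00588 with the clock score in the Ad-TGFβ1 model.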

Other observations

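The lungs look male by 2 genes, although the labels say mice of both sexes. Xist, the RNA of the inactive X chromosome, had at most 12 counts in any of the 40 libraries and a median of 5, and Ddx3y, a Y-linked helicase gene, had 699 to 2234. Changes in gene counts with Xist as a covariate therefore do not show dependence on sex.

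Some lists are not described above. With bleomycin, genes of alveolar macrophages rose in 11 and fell in 3 of 18 cases, or 12 and 3 adjusted over the list alone (camera adjusted p = 2.03e-05, and adjusted p = 0.312 with an estimated correlation). MHC class II genes rose in 7 of 10, 8 adjusted over the list alone (camera adjusted p = 7.42e-06, and adjusted p = 0.27 with an estimated correlation). Nuclear genes of oxidative phosphorylation fell with saracatinib in bleomycin lungs in 10 of 29, 15 adjusted over the list alone (camera adjusted p = 8.49e-08, and adjusted p = 0.406 with an estimated correlation). Alveolar type 1 genes rose with Ad-TGFβ1 in 9 and fell in 1 of 16, or 13 and 1 adjusted over the list alone (camera adjusted p = 1.1e-06, and adjusted p = 0.276 with an estimated correlation).

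The part by which saracatinib moved the bleomycin changes back, with its jackknife standard error, was 91.9 ± 13.0% for collagens, 84.2 ± 14.8% for TGF-beta genes, 83.4 ± 12.6% for cell cycle genes and 30.3 ± 14.0% for p53 targets. It was 4.89 ± 21.5% for T cell genes and -0.712 ± 19.5% for MHC class II genes. Only 24 of the 49 lists were measured, those called by camera with a median bleomycin change of at least 0.5 in size, and among these the lowest were plasma cell genes at -24.9 ± 45.6% and alveolar type 1 genes at -28.5 ± 24.1%. For collagens, splits of the vehicle libraries gave 39.9 to 209%. These are ratios of differences in the mean log2 CPM of a list and were chosen after the results were seen.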
